A study of Homo sapiens with 12 samples.

How the data were processed

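RNA of 12 samples, labelled as Hep3B or Huh7 cells 48 h after transfection with an siRNA or negative control RNA, was measured with 1 array each, 3 arrays per group. The deposited table holds 1 column per array in log2 units, per the values themselves and the authors' processing notes, which name Agilent Feature Extraction 10.7.1.1. The labels conflict on this point: they also give a standard Affymetrix labelling protocol and a Cy3 label, and the row names are Affymetrix transcript cluster names. How probes were summarised, and whether arrays were normalized to each other, is not stated. The labels do not say whether the 3 arrays of a group came from separate cultures, so p-values measure only the spread between arrays. Replicate numbers were not used as pairs.

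The table has 70523 rows, of which 67528 transcript cluster rows were kept and 2995 control, exon, junction and numbered rows were left out of the comparisons. The probe table pairs 23781 of 25324 probes with 1 gene symbol. Of 479 symbols with more than 1 probe, the probe with the highest mean over all arrays was kept, and the 42204 transcript clusters with no symbol and the 1543 probes with several stayed as rows of their own, which gave 66212 tested rows with 22465 named genes. Rows carry no coordinates here, since no genome build is stated. No filter on dim rows was used. Deposited values reached a ceiling of 19.9, and 48 tested rows had a mean over 19. Because array medians differed by 0.124, more than the limit of 0.1 set in advance, arrays were quantile normalized with limma.

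Analyses used R 4.3.3 with limma 3.58.1 and statmod 1.5.0, and figures Python 3.11.15 with matplotlib 3.10.9. A linear model with 1 mean per group was fitted over all 12 arrays (8 residual degrees of freedom), with empirical Bayes moderation and a trend of the spread with the mean. The 5 comparisons were siRNA against control in Hep3B, the same in Huh7, the mean of both effects, their difference (Huh7 minus Hep3B) and Huh7 control against Hep3B control. P-values were two-sided and adjusted by Benjamini-Hochberg over all rows of a comparison, with a threshold of 0.05, and "called" means past it. The 37 gene lists on the cell cycle, stress, liver function, metabolism, signalling, upkeep and markers of other cell types were tested with limma camera at a preset correlation of 0.01, adjusted over the 37 lists. Of 865 listed members 750 were measured. Camera with an estimated correlation and fry stood beside it. Member counts are given over all rows and adjusted over the list alone. Some genes stand in more than 1 list, so lists are not independent.

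The comparisons, lists, normalization rule, the rule for named genes and the alternatives other than cyclic loess and camera among rows above background were chosen before the data were examined. That rule took, per siRNA comparison and for the mean effect, the 10 largest changes each way among named genes past the threshold, with all siRNA arrays on one side of all control arrays of that line and 1 group mean above the median of all rows, and up to 4 members of each called list. For the difference it took 5 each way, and for the control arrays 10 each way with AFP, ALB and GPC3. FGA in Hep3B, FGA and FGB in Huh7 as examples of a call in opposite directions, and NCL, FOXA2, GCLM, TKT, ALDOC, ACSL1, BCL2L11 and BMF in the difference, were added after their values were seen. XIST and Y-linked genes were left out of the named genes. Alternatives were the deposited values, median centring, cyclic loess, filters on dim rows, the mean of probes or every probe, a 2-fold minimum, array weights, no trend of the spread, replicate blocks, only the arrays compared, and leaving out each array in turn. Rows above background means named rows brighter than the highest of 23 background rows.

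The procedure was tested on simulated data of 66212 rows. It recovered 58% of changes of 0.5 log2 units and 98% of changes of 1 in the Hep3B comparison, 52% and 92% in Huh7, and 16% and 80% in the difference. Changes were put only into named rows brighter than the median of all rows, with independent normal errors and no normalization step. The rates need not hold for dim or unnamed rows. The number of arrays limits the precision.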

Results

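RNA levels were measured on 12 arrays of Hep3B and Huh7 cells, both established lines from human liver cancer, 48 h after transfection with an siRNA or with a negative control RNA. Each line had 3 siRNA arrays and 3 control arrays. According to the series title the study is about 1 long non-coding RNA, and the siRNA comparisons ask which transcripts differ when the siRNA is given. The level of that RNA itself is not analysed here, because no row could be matched to it by name. Array medians ran from 3.82 to 3.94 on the log2 scale as deposited. The 23 background rows had a median of 3.36 and a highest mean of 5.50, and 14629 of the 66212 tested rows lay above that level. Arrays of the same group correlated across rows with r from 0.991 to 0.994, arrays of the same line under the other treatment with r from 0.983 to 0.988, and arrays of different lines with r from 0.947 to 0.961. The description of Huh7 control array 1 names Hep3B, while its title, source and cell line name Huh7. Its values correlated with the other Huh7 arrays at r from 0.985 to 0.993 and with the Hep3B arrays at r from 0.954 to 0.960. The number of arrays limits the precision. Errors after a log2 change are standard errors (SE, n = 3 arrays per group).

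In Hep3B cells the siRNA raised small nuclear RNA rows and ANKRD1, GDF15, EREG and EGR1, and lowered mitotic genes, ATP10D and the secreted proteins C5 and KNG1. RNU12, the U12 RNA of the minor spliceosome, rose by 5.05 ± 0.20 on the log2 scale (adjusted p = 2.73e-07), a lower bound because its control level of 3.65 lay within background. RNU11, its U11 partner, rose by 3.57 ± 0.33. The 5 rows of U3, the small nucleolar RNA of early ribosomal RNA cleavage, rose by 4.11 (SNORD3C) to 4.66 (SNORD3B-1 and SNORD3B-2). Rows of U1 copies rose by 5.06 (RNU1-12P and RNU1-13P) and 3.74 (RNU1-18P). Which copy gave the signal is uncertain, since RNU1-12P and RNU1-13P, and likewise SNORD3B-1 and SNORD3B-2, held identical values on all 12 arrays. ATP10D, a phospholipid flippase, fell by 2.60 ± 0.09 on the log2 scale (adjusted p = 1.65e-07). DBR1, the enzyme that opens intron lariats, fell by 1.92 ± 0.10. The complement protein C5 fell by 1.89 ± 0.06, the secreted protease HABP2 by 2.03 ± 0.17 (log2 change -2.03) and kininogen, KNG1, by 1.77 ± 0.16 (log2 change -1.77). Other large falls were in the amino acid transporter SLC6A14 (-2.07), ERP27 (-2.37), the cohesin acetyltransferase ESCO2 (-1.81) and the small nucleolar RNAs SNORD41 (-2.37) and SNORD105B (-1.89).

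Among the fixed gene lists, mitosis genes fell together in Hep3B: 26 of 29 members of the cell cycle G2/M list fell, and 28 when adjusted over the list alone (camera adjusted p = 1.49e-33, 0.0116 with an estimated correlation). KIF23, a kinesin of cytokinesis, fell by 1.74 ± 0.12, and the checkpoint kinase BUB1 (-1.32), the mitotic kinase CDK1 (-1.21) and the proliferation marker MKI67 (-1.20) fell too. Of 33 DNA replication and S phase genes, 11 fell and 1 rose (16 and 2 adjusted over the list alone), among them TK1 (-1.27) and RRM2 (-0.86), both enzymes of nucleotide supply. That list had an adjusted p of 1.76e-05 (adjusted p = 0.167 with an estimated correlation). YAP/TAZ targets rose, 11 of 18 over all rows and 15 adjusted over the list alone, with ANKRD1 at 3.26 ± 0.12, AJUBA at 1.73 and MYOF at 1.05 (adjusted p = 8.21e-14, and adjusted p = 0.0123 with an estimated correlation). Control levels of ANKRD1 (5.06) and MYOF (4.49) lay within background in Hep3B, so these rises are lower bounds. Immediate early and growth factor response genes rose in 14 of 25 cases (16 adjusted over the list alone), with the growth factor EREG at 3.23 ± 0.22 and the transcription factors EGR1 at 2.99 ± 0.16 and KLF6 at 1.92 (adjusted p = 1.82e-15, and adjusted p = 0.0254 with an estimated correlation). MYC targets and ribosome biogenesis genes rose in 15 of 24 cases (18 rose and 1 fell adjusted over the list alone), with the nucleolar protein NOLC1 at 2.14 ± 0.09, MYC at 1.74 and UTP20 at 0.89 (adjusted p = 4.4e-14, and adjusted p = 0.0116 with an estimated correlation).

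The ATF4 and NRF2 lists, TGF-beta targets and histones were also called higher in Hep3B, where control levels of DDIT4, AKR1B10 and JUNB lay within background and make their rises lower bounds. In the ATF4 and amino acid response list 18 of 29 members rose (20 adjusted over the list alone), led by the stress cytokine GDF15 at 3.16 ± 0.25, the cystine transporter SLC7A11 at 2.78 (3.39 without Hep3B siRNA array 1) and the mTORC1 inhibitor DDIT4 at 2.35. Its adjusted p was 3.1e-17 (adjusted p = 0.0985 with an estimated correlation). NRF2 and oxidative stress genes went both ways, with 8 of 20 higher and 3 lower (9 and 4 adjusted over the list alone), and included AKR1B10 at 2.33 and ME1 at 1.06. The adjusted p of 0.0128 became 0.391 as adjusted p with an estimated correlation, and 0.0757 as adjusted p with only the 6 Hep3B arrays. TGF-beta/SMAD targets showed 6 of 18 higher and 2 lower (7 and 2 adjusted over the list alone), with JUNB at 2.22, SKIL at 1.29 and ID2 at -0.72 (adjusted p = 0.00304). The adjusted p was 0.0985 with an estimated correlation and 0.116 among rows above background. Of 10 replication-dependent histone genes 2 rose, also adjusted over the list alone, namely H1-4 at 1.30 ± 0.15 and H4C3 at 0.98 (adjusted p = 0.000808, and adjusted p = 0.151 with an estimated correlation).

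Lists of secreted proteins, acute phase proteins, cholesterol biosynthesis and glycolysis were called lower in Hep3B, although FGA and FGB rose. Hepatocyte secreted proteins fell in 9 of 21 cases and rose in 2, with the same counts adjusted over the list alone (adjusted p = 8.33e-05, and adjusted p = 0.149 with an estimated correlation). Transthyretin, TTR (-1.62), and AMBP (-1.29) fell, while the fibrinogen chains FGB at 1.57 ± 0.13 and FGA (from a mean of 13.96 to 15.06) rose. Acute phase proteins fell in 5 of 20 cases, including C3 (-1.59) and CP (-1.44), and rose in 2, with the same counts adjusted over the list alone. Their adjusted p of 0.0206 became 0.0524 without Hep3B siRNA array 1, 0.101 among rows above background and 0.167 as adjusted p with an estimated correlation. Cholesterol biosynthesis genes fell in 5 of 20 cases and rose in 1 (10 and 1 adjusted over the list alone), with MSMO1 at -0.98, STARD4 at -0.58 and the feedback regulator INSIG1 at 0.66. Their adjusted p of 0.0031 became 0.0576 after median centring and 0.167 as adjusted p with an estimated correlation. Glycolysis and hypoxia genes fell in 11 of 28 cases and rose in 2 (12 and 3 adjusted over the list alone), with the collagen hydroxylase P4HA1 at -1.20, PDK1 at -1.14 and BNIP3 at -1.09 (adjusted p = 6.22e-05, and adjusted p = 0.135 with an estimated correlation).

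The oxidative phosphorylation, ribosomal protein and housekeeping lists were also called lower in Hep3B. Oxidative phosphorylation genes fell in 8 of 26 cases and rose in 1 (10 and 1 adjusted over the list alone), with COX5A at -0.85 and NDUFA2 at -0.56, which ended within background (adjusted p = 3.07e-05, and adjusted p = 0.0985 with an estimated correlation). Among 21 cytosolic ribosomal proteins 1 fell, RPS9 at -0.44, and 9 fell adjusted over the list alone (adjusted p = 7.56e-05, and adjusted p = 0.0675 with an estimated correlation). Housekeeping genes fell in 6 of 14 cases, also adjusted over the list alone, with B2M at -0.91 and GUSB at -0.73 (adjusted p = 6.21e-06, and adjusted p = 0.0985 with an estimated correlation). A further 20 lists passed no threshold, and 1 list is not used here. Adjusted p was 0.145 for apoptosis regulators, 0.284 for the type I interferon response and for the unfolded protein response, 0.271 for xenobiotic and bile acid metabolism and 0.154 for NF-kB and inflammatory genes. Autophagy and lysosome genes, hepatocyte transcription factors, epithelial-mesenchymal transition genes, Wnt/beta-catenin targets and the RNA interference machinery each had an adjusted p of 0.389. Adjusted p was 0.141 for fetal liver markers, 0.187 for fatty acid synthesis, 0.756 for fatty acid oxidation, 0.915 for gluconeogenesis, 0.478 for heat shock proteins and 0.577 for metallothioneins. Markers of other cell types had adjusted p of 0.328 (fibroblast and stellate), 0.915 (endothelial), 0.919 (blood and macrophage) and 0.865 (cholangiocyte). In all, 6810 of 66212 rows changed in Hep3B, 3727 up and 3083 down, and 3797 of these were named genes (2091 up and 1706 down). The upward share was 54.7% of called rows, and 65.9% after median centring of the arrays in place of quantile normalization.

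In Huh7 cells the siRNA raised the same U3 rows, 9 of 11 U1 rows and ANKRD1, and lowered mitotic genes, the fibrinogen chains, albumin and the tumour markers AFP and GPC3. U3 rows rose by 3.44 (SNORD3C) to 4.36 (SNORD3B-1 and SNORD3B-2), with the same doubt about which copy gave the signal. ANKRD1, a YAP target, rose by 4.19 ± 0.12 (adjusted p = 4.92e-08). Rows of U1 copies rose by 2.69 (RNU1-12P and RNU1-13P), 2.48 (RNU1-11P) and 2.43 (RNU1-10P). CTSE, an aspartic protease, fell by 2.39 ± 0.28 on the log2 scale, KNG1 by 1.75 ± 0.16 (log2 change -1.75) and the mitotic kinesin KIF20A by 1.70 ± 0.08 (log2 change -1.70). The hepatocyte transcription factor ONECUT1 (-1.62), FAM111B (-1.73), P4HA1 (-1.53) and the sulfotransferase SULT2A1 (-1.56), which ended within background, fell too. Falls of APOH (-1.53) and the short gene segment IGHD3-10 (-1.54) were less secure. For APOH the adjusted p was 0.0562 without Huh7 control array 2 and 0.0731 without Huh7 control array 3. That of IGHD3-10 was 0.0739 and 0.0877 without the same arrays, 0.0665 without Huh7 siRNA array 1 and 0.0756 without Huh7 siRNA array 3.

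The cell cycle G2/M list fell in Huh7 as well, in 27 of 29 members (28 adjusted over the list alone), with HMMR at -1.13, cyclin B1, CCNB1, at -1.10 and CENPF at -1.10 (adjusted p = 1.93e-38, and adjusted p = 0.00908 with an estimated correlation). DNA replication and S phase genes fell in 16 of 33 cases (18 adjusted over the list alone), with the helicase subunit MCM6 at -0.89 and CCNE2 at -0.84 (adjusted p = 8.25e-15, and adjusted p = 0.0239 with an estimated correlation). YAP/TAZ targets rose in 12 of 18 cases (14 rose and 1 fell adjusted over the list alone), with AJUBA at 1.69, CCN1 at 1.57 and MYOF at 1.57 (adjusted p = 2.1e-15, and adjusted p = 0.0118 with an estimated correlation). Immediate early genes rose in 11 of 25 cases (13 adjusted over the list alone), with the phosphatase DUSP1 at 1.13, PHLDA1 at 0.94 and KLF6 at 0.83 (adjusted p = 2.46e-12, and adjusted p = 0.0239 with an estimated correlation). MYC targets and ribosome biogenesis genes rose in 5 of 24 cases and fell in 1 (7 and 3 adjusted over the list alone), with NOLC1 at 1.84 ± 0.09 and MYC at 0.95. An adjusted p of 0.00214 was 0.125 as adjusted p with an estimated correlation and 0.092 among rows above background. In the ATF4 list 12 of 29 members rose and 1 fell (14 and 3 adjusted over the list alone), with SESN2 2.15-fold higher and the serine synthesis enzyme PSAT1 at -1.21 lower (adjusted p = 1.1e-05, and adjusted p = 0.304 with an estimated correlation).

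Lists of secreted proteins, acute phase proteins, hepatocyte transcription factors, fetal liver markers and gluconeogenesis were called lower in Huh7. Hepatocyte secreted proteins fell in 11 of 21 cases (13 fell and 1 rose adjusted over the list alone), including albumin, ALB, at -1.10 ± 0.05 (adjusted p = 1.03e-09, and adjusted p = 0.0239 with an estimated correlation). Acute phase proteins fell in 8 of 20 cases (12 adjusted over the list alone), with FGG at -1.28, FGA at -1.04 and ORM1 at -0.79 (adjusted p = 3.11e-08, and adjusted p = 0.0137 with an estimated correlation). Of 14 hepatocyte transcription factors 4 fell (5 adjusted over the list alone), with NR5A2 at -0.73 beside ONECUT1 (adjusted p = 0.00214, and adjusted p = 0.127 with an estimated correlation). Fetal liver and tumour markers fell in 5 of 17 cases (5 fell and 1 rose adjusted over the list alone), with AFP at -1.26 ± 0.16, GPC3 at -1.15 ± 0.11 and IGF2BP3 at -0.60. The adjusted p of 0.00769 was 0.0424 as adjusted p with an estimated correlation and 0.21 among rows above background. Gluconeogenesis and amino acid metabolism genes fell in 4 of 20 cases, also adjusted over the list alone, with the urea cycle enzyme CPS1 at -1.45 and HGD at -0.79 (adjusted p = 0.0116, and adjusted p = 0.188 with an estimated correlation).

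Lists of lipid, energy and housekeeping genes and ribosomal proteins were called lower in Huh7 too. Cholesterol biosynthesis genes fell in 11 of 20 cases (13 adjusted over the list alone), with MSMO1 at -1.18, DHCR7 at -0.93 and STARD4 at -0.81 (adjusted p = 5.93e-13, and adjusted p = 0.0128 with an estimated correlation). Glycolysis and hypoxia genes fell in 14 of 28 cases and rose in 1 (16 and 1 adjusted over the list alone), with P4HA1 at -1.53, BNIP3 at -1.51 and PDK1 at -1.17 (adjusted p = 8.17e-13, and adjusted p = 0.0137 with an estimated correlation). Oxidative phosphorylation genes fell in 11 of 26 cases (21 adjusted over the list alone), with UQCRC2 at -0.83 and ATP5F1B at -0.77 (adjusted p = 2.46e-12, and adjusted p = 0.0137 with an estimated correlation). Cytosolic ribosomal proteins fell in 6 of 21 cases (12 adjusted over the list alone), with RPS3 at -0.47 (adjusted p = 1.69e-07, and adjusted p = 0.0137 with an estimated correlation), although RPS3 alone had an adjusted p of 0.0726 with only the 6 Huh7 arrays. Housekeeping genes fell in 7 of 14 cases (8 adjusted over the list alone), with the RNA polymerase subunit POLR2A at -1.25, PGK1 at -0.89 and HPRT1 at -0.55 (adjusted p = 1.46e-08, and adjusted p = 0.0239 with an estimated correlation). Fatty acid synthesis and lipid storage genes fell in 7 of 22 cases and rose in 2, with the same counts adjusted over the list alone, and included ACSL4 at -1.28 and ELOVL6 at -0.63. The adjusted p of 0.00214 was 0.0934 as adjusted p with an estimated correlation and 0.0676 among rows above background.

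A further 5 lists were called in Huh7. Type I interferon response genes rose in 5 of 34 cases (7 adjusted over the list alone), with the RNA sensor OAS3 at 0.59, EIF2AK2 at 0.55 and OAS1 at 0.51 (adjusted p = 0.00196). Control levels of OAS3 and OAS1 lay within background, and OAS1 stayed there with siRNA (5.479, 5.302 and 5.176). The adjusted p was 0.154 with an estimated correlation and 0.1 among rows above background. Fatty acid oxidation genes fell in 7 of 20 cases and rose in 2 (9 and 4 adjusted over the list alone), with CPT1A at -0.89 and FABP1 at -0.73. Their adjusted p of 0.0314 was 0.0555 without Huh7 control array 3, 0.0551 without Huh7 siRNA array 1, 0.199 on the deposited values, 0.247 after median centring and 0.201 as adjusted p with an estimated correlation. TGF-beta/SMAD targets rose in 4 of 18 cases and fell in 1 (6 and 1 adjusted over the list alone), with CDKN2B at 0.76, from a control level within background, and ID2 at -1.03. The adjusted p of 0.0258 was 0.0597 without Huh7 control array 1, 0.0504 without Huh7 control array 2, 0.1 without Huh7 siRNA array 3 and 0.136 as adjusted p with an estimated correlation. Histone genes had 1 of 10 members lower, also adjusted over the list alone, H1-4 at -0.95 (adjusted p = 0.0258). That adjusted p was 0.18 without Huh7 control array 2, 0.187 without Huh7 siRNA array 3 and 0.277 as adjusted p with an estimated correlation. Heat shock proteins fell in 4 of 16 cases and rose in 1 (5 and 2 adjusted over the list alone), with HSPA4L at -0.87 (adjusted p = 0.0437, and adjusted p = 0.116 with an estimated correlation). Their adjusted p was 0.0515 and 0.0559 without Hep3B siRNA arrays 2 and 3, 0.0759 and 0.0607 without Huh7 control arrays 1 and 2, 0.0583 without Huh7 siRNA array 1 and 0.123 on the deposited values.

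A further 14 lists passed no threshold in Huh7, and 1 list is not used here. Adjusted p was 0.363 for apoptosis regulators, 0.344 for NF-kB and inflammatory genes, 0.648 for xenobiotic and bile acid metabolism, 0.843 for the unfolded protein response and 0.904 for NRF2 targets and for autophagy and lysosome genes. It was 0.426 for metallothioneins, 0.634 for epithelial-mesenchymal transition genes, 0.54 for Wnt/beta-catenin targets and 0.315 for the RNA interference machinery. Markers of other cell types had adjusted p of 0.503 (fibroblast and stellate), 0.516 (endothelial), 0.704 (blood and macrophage) and 0.344 (cholangiocyte). In all, 5327 of 66212 rows changed in Huh7, 3019 up and 2308 down, and 3082 of these were named genes (1532 up and 1550 down). With the 6 Huh7 arrays alone 2725 rows changed. The upward share was 56.7% of called rows, and 70.1% after median centring.

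**Figure D1:**
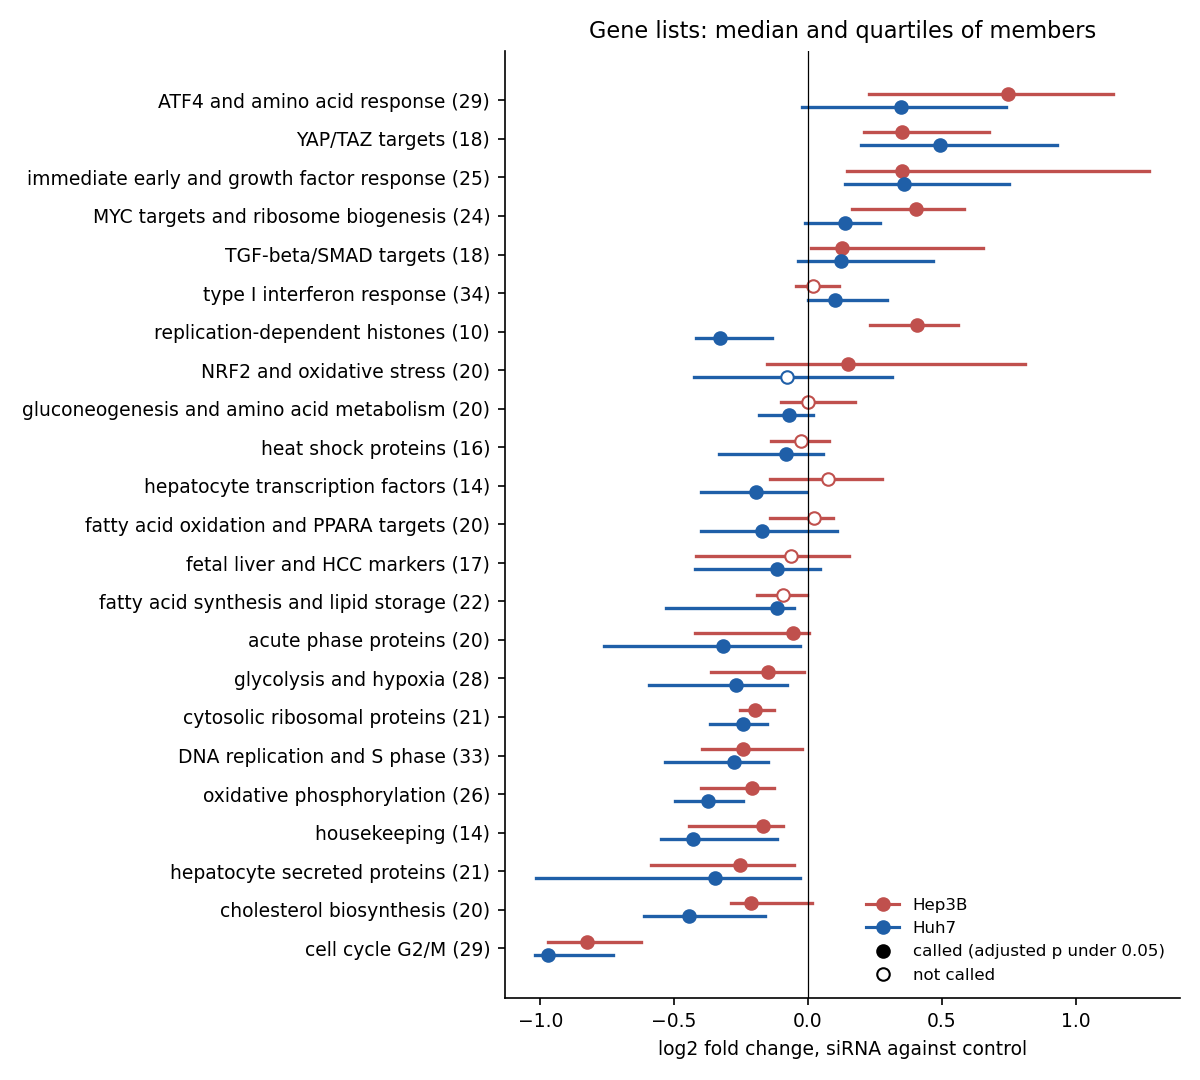
Log2 fold change of siRNA against control (x axis) for each gene list called in at least 1 line, with the number of measured members in brackets; circles are medians, bars run from the lower to the upper quartile of the members, and open circles mark lists not called in that line. The cell cycle G2/M medians were -0.82 in Hep3B and -0.97 in Huh7, and the ATF4 medians 0.75 and 0.35.

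The mean of both lines' effects asks which genes changed across the lines. Mitotic genes, C5, KNG1 and GPC3 were lower and the U3 rows, ANKRD1, NOLC1 and AJUBA higher. C5 fell by 1.62 ± 0.05 (adjusted p = 2.04e-08), GPC3, a cell surface proteoglycan of fetal liver, by 1.34 ± 0.08 (log2 change -1.34), and the complement inhibitor SERPING1 by 1.49 ± 0.14 (log2 change -1.49). NAALAD2 (-1.48), FAM111B (-1.54), HABP2 (-1.52) and the row named for the pseudogene FABP5P7 (-1.50), whose source transcript is uncertain, fell too. ANKRD1 rose by at least 3.73 (adjusted p = 3.96e-09), a lower bound because its Hep3B control level lay within background. NOLC1 rose by 1.99 ± 0.06, AJUBA by 1.71 ± 0.07 and MYC by 1.34 ± 0.11. The antiviral RNA sensor RIGI at 0.37 was among 6 of 34 interferon response genes that rose (8 adjusted over the list alone), and no member of the 6 was called in both lines.

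Of the lists, 17 were called in the mean effect, 6 higher and 11 lower, and 12 of the 17 held with an estimated correlation. G2/M genes fell in 28 of 29 cases, also adjusted over the list alone (adjusted p = 5.03e-37, and adjusted p = 0.0103 with an estimated correlation), and S phase genes, oxidative phosphorylation genes and cytosolic ribosomal proteins were lower (adjusted p = 0.0439, 0.0221 and 0.0158 with an estimated correlation). Immediate early genes rose in 19 of 25 cases and 20 adjusted over the list alone (adjusted p = 1.1e-17, and adjusted p = 0.0158 with an estimated correlation), and YAP/TAZ targets in 12 of 18, or 15 adjusted over the list alone (adjusted p = 3.51e-16, and adjusted p = 0.0104 with an estimated correlation). MYC targets were also higher (adjusted p = 0.0158 with an estimated correlation). Secreted proteins, acute phase proteins, cholesterol biosynthesis, glycolysis and housekeeping genes were lower (adjusted p = 0.044, 0.027, 0.026, 0.027 and 0.027 with an estimated correlation). With an estimated correlation the adjusted p was 0.102 for the ATF4 list, 0.0665 for TGF-beta targets, 0.0691 for fetal liver markers, 0.182 for fatty acid synthesis and 0.229 for the interferon list. The fatty acid synthesis list, with ACSL4 at -0.91 and ELOVL5 at -0.83, had an adjusted p of 0.0221 that was 0.0571 without Hep3B siRNA array 1, 0.0591 without Huh7 siRNA array 2 and 0.18 on the deposited values. For fetal liver markers it was 0.025, and 0.141 on the deposited values. Among rows above background the interferon list had an adjusted p of 0.393 and TGF-beta targets of 0.137.

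The mean effect passed the threshold in 9542 rows, 5121 up and 4421 down, of which 5150 were named genes (2644 up and 2506 down). The upward share was 53.7% of called rows, and 66.4% after median centring. Of the rows called in each line, 2815 were called in both, and 2751 of these (97.7%) went the same way. Rows higher in both numbered 1540 against 169.9 if the calls were independent, and rows lower in both 1211 against 107.5. That expectation counts all 66212 rows, of which 14629 lay above background, and was not computed among those alone. Calls in both lines also used the same spread per row. The excess therefore does not measure a shared response alone. Across rows, which are not independent replicates, the effects in both lines correlated with r = 0.567 and rho = 0.367, and no array entered both effects. Across named genes r was 0.653 and rho 0.491.

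**Figure D2:**
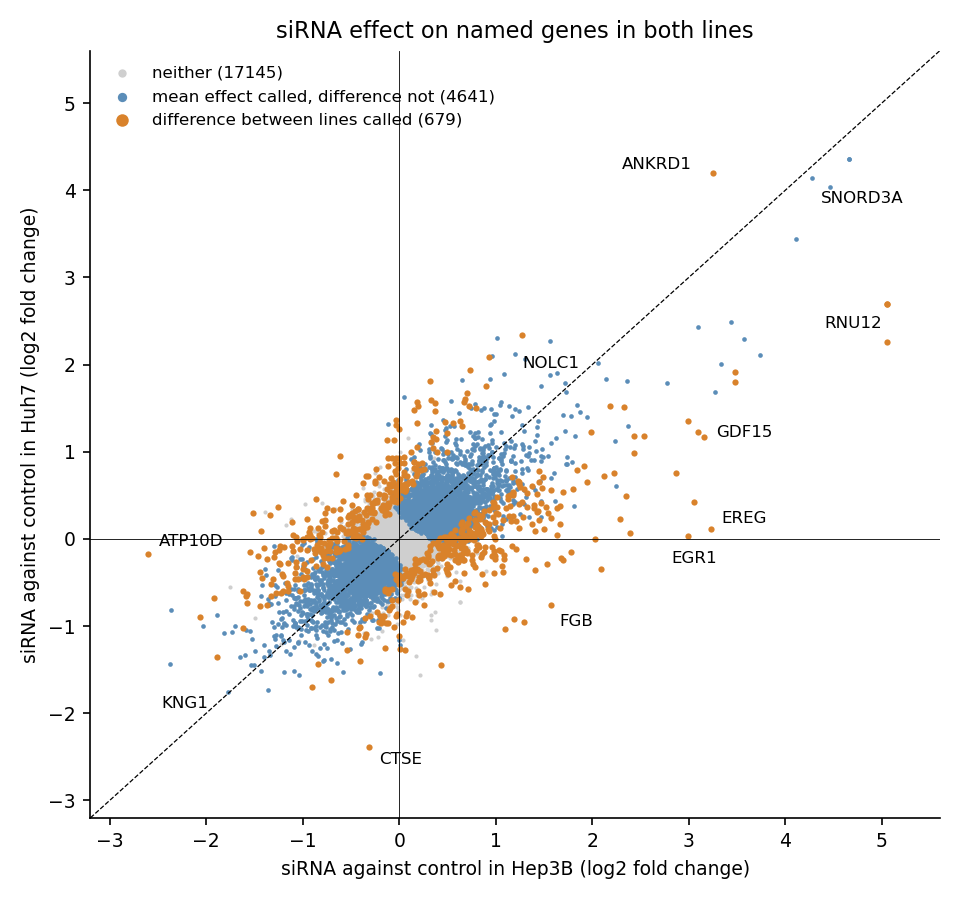
Log2 fold change of siRNA against control in Hep3B (x axis) and Huh7 (y axis), 1 point per named gene; the dashed line marks equal effects, blue points are 4641 genes called in the mean effect and not in the difference, and orange points are 679 genes called in the difference. ANKRD1 and SNORD3A lay high in both lines, while EREG, EGR1 and FGB rose in Hep3B and not in Huh7.

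**Figure D3:**
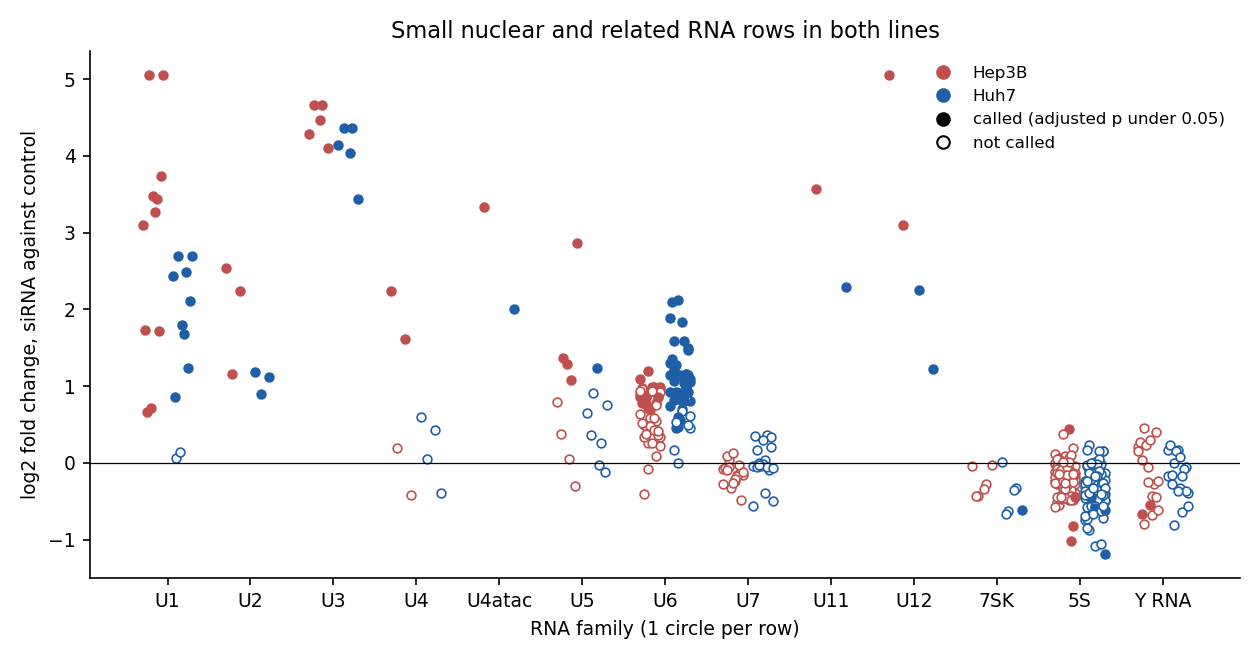
Log2 fold change of siRNA against control (y axis) for rows of small RNA families (x axis) with a group mean above the highest background row; red circles are Hep3B, blue circles Huh7, and filled circles passed the test. Median changes of the 5 U3 rows were 4.47 in Hep3B and 4.14 in Huh7. The 19 U7 rows, all named for pseudogenes, had medians of -0.11 and -0.02, the latter 0.03 on the deposited values.

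Growth response genes, FGA, FGB and ATP10D were among the genes that passed the test of the difference between the lines, Huh7 effect minus Hep3B effect. EREG (-3.11 ± 0.32, adjusted p = 0.0011) and EGR1 (-2.95 ± 0.23, adjusted p = 0.000403) rose in Hep3B, and in Huh7 both lay under the highest background row, EGR1 at 4.23 in controls and 4.26 with siRNA, EREG at 4.36 and 4.48. ARRDC3, an arrestin family protein, rose by 2.09 in Hep3B and had a log2 change of -0.34 in Huh7 (difference -2.44 ± 0.12, adjusted p = 2.68e-05). FGB and FGA rose in Hep3B and fell in Huh7 (-0.76 and -1.04), as did the linker histone H1-4, with differences of -2.33, -2.14 and -2.25. RNU12 rose less in Huh7 (difference -2.80 ± 0.28), with control levels of 3.65 in Hep3B and 3.68 in Huh7 that lay within background. SNORD121B had a difference of -2.63 ± 0.29 with control levels of 3.79 and 4.06, also within background. ATP10D (difference 2.43 ± 0.13, adjusted p = 3.7e-05) and the stem cell marker PROM1 (1.61 ± 0.13, adjusted p = 0.000403) fell in Hep3B and not in Huh7, where their log2 changes were -0.17 and 0.27. HEG1, a receptor of endothelial junctions, fell by 0.61 in Hep3B and rose by 0.95 in Huh7 (difference 1.56 ± 0.14, adjusted p = 0.00059). The imprinted small nucleolar RNAs SNORD116-1 and SNORD116-2 differed by 1.62 and 1.81, but lay within background in both Huh7 groups, where a fall would not have been seen. SNORD116-2 had an adjusted p of 0.0676 with replicate blocks within lines.

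Of the lists, 12 were called in the difference, each with a lower siRNA effect in Huh7, meaning a smaller rise or a deeper fall, not a lower level. With an estimated correlation limma camera called 0 of them, with 7 lists at an unadjusted p under 0.05, and fry called 19. ATF4 genes had 6 of 29 lower (10 lower and 1 higher adjusted over the list alone; adjusted p = 4.49e-08, and adjusted p = 0.322 with an estimated correlation), including GDF15 (-1.99), CHAC1 (-1.93) and DDIT4 (-1.86). In Huh7 CHAC1 lay within background in both groups and DDIT4 in the controls. MYC targets had 2 of 24 lower (5 adjusted over the list alone; adjusted p = 4.49e-08), histones 2 of 10 (3; adjusted p = 4.72e-06), cholesterol genes 1 of 20 (7; adjusted p = 1.7e-06) and hepatocyte transcription factors 2 of 14 (6; adjusted p = 1.92e-05), each with an adjusted p of 0.121 with an estimated correlation. The members past the threshold were NCL (-0.61), ODC1 (-0.72), H1-4, H4C3 (-1.37), INSIG1 (-0.71), FOXA2 (-0.52) and ONECUT1 (-0.91). NRF2 genes had 3 of 20 lower, AKR1B10 (-0.82), GCLM (-1.06) and TKT (-0.54), with 7 lower and 2 higher adjusted over the list alone (adjusted p = 9.15e-05, and adjusted p = 0.273 with an estimated correlation). Glycolysis genes had 1 of 28 lower, ALDOC at -0.43 (3 adjusted over the list alone; adjusted p = 2.45e-05, and adjusted p = 0.174 with an estimated correlation) and fatty acid oxidation genes 2 of 20, CPT1A at -0.96 and ACSL1 at -0.60 (7 lower and 1 higher adjusted over the list alone; adjusted p = 0.0107, and adjusted p = 0.258 with an estimated correlation).

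The other 4 lists called in the difference lost the call without some single arrays. S phase genes had 2 of 33 lower, MCM6 (-1.02) and CCNE2 (-0.61), with 5 lower and 1 higher adjusted over the list alone. Their adjusted p of 0.0155 was 0.0989 without Huh7 control array 3, 0.063 without Huh7 siRNA array 1 and 0.397 as adjusted p with an estimated correlation. Apoptosis regulators had 2 of 24 lower, BCL2L11 (-1.06) and BMF (-0.87), also adjusted over the list alone, and their adjusted p of 0.0212 was 0.0594 without Huh7 siRNA array 1 and 0.121 as adjusted p with an estimated correlation. Oxidative phosphorylation genes had 0 of 26 past the threshold by limma, also adjusted over the list alone, and 4 lower at an unadjusted p under 0.05. Their adjusted p of 0.0207 was 0.077 without Hep3B siRNA array 1, 0.0612 without Huh7 control array 3, 0.0981 without Huh7 siRNA array 1 and 0.345 as adjusted p with an estimated correlation. Immediate early genes had 5 of 25 lower, among them JUNB (-1.47) and KLF6 (-1.08), and 1 higher (7 and 4 adjusted over the list alone). Their adjusted p of 0.0338 was 0.0945 without Hep3B control array 1, 0.0753 without Hep3B siRNA array 3, 0.0662 without Huh7 control array 3, 0.0594 without Huh7 siRNA array 1, 0.0828 without Huh7 siRNA array 3, 0.0557 on the deposited values and 0.397 as adjusted p with an estimated correlation.

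In the difference 1240 rows passed the threshold, 626 higher and 614 lower, of which 679 were named genes (316 and 363). The count fell to 723, 616 and 627 without Hep3B control array 1, 2 or 3, to 760 and 725 without Hep3B siRNA array 2 or 3, and to 823 without Huh7 siRNA array 1. It was 312 with replicate blocks within lines, 721 after median centring and 1957 with rows dimmer than the median left out.

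**Figure D4:**
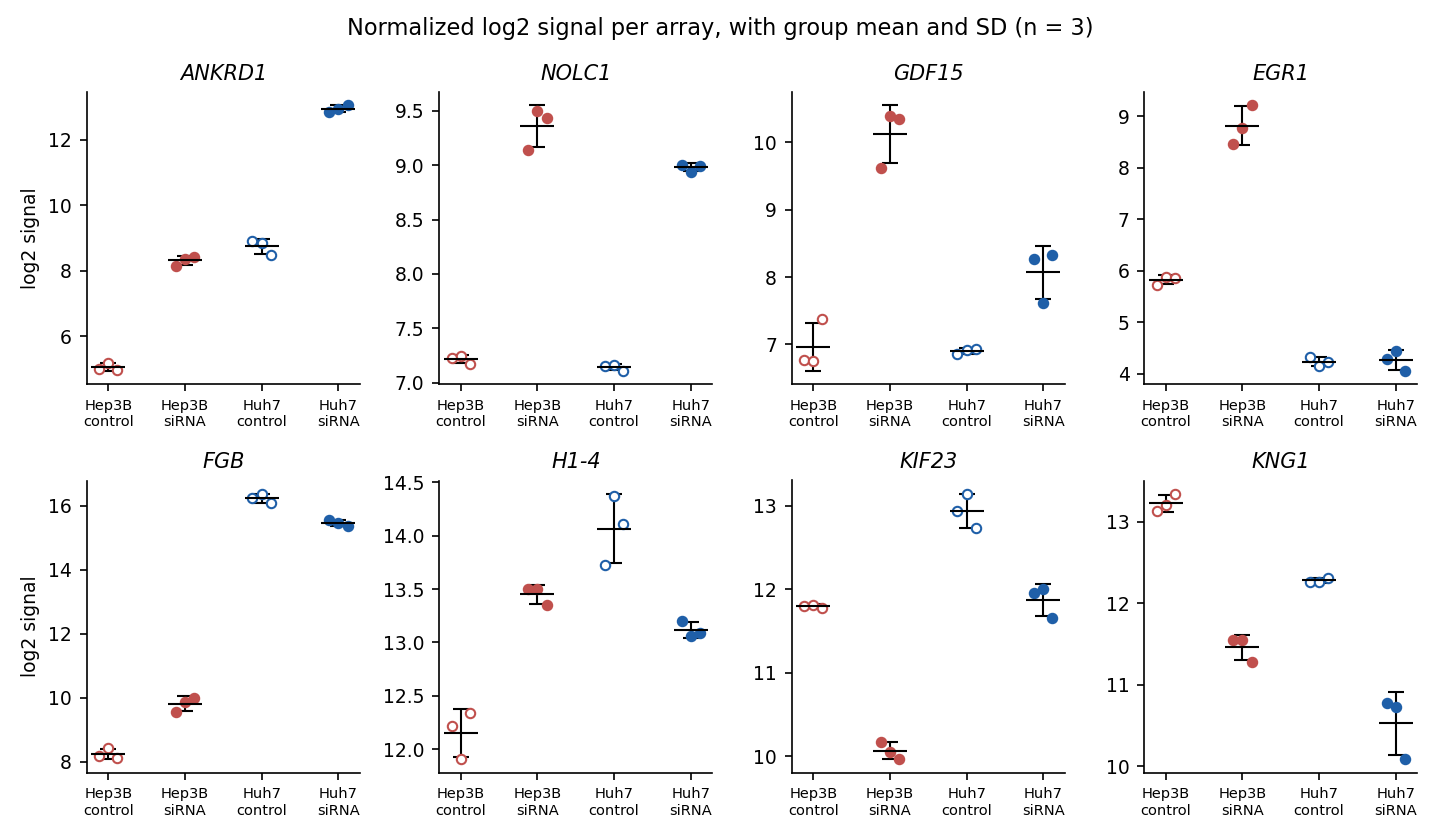
Normalized log2 signal (y axis) of 8 named genes in the 4 groups (x axis), 1 circle per array, open for control and filled for siRNA, with the group mean as a line and the SD as bars (n = 3). FGB and H1-4 rose in Hep3B and fell in Huh7, while ANKRD1 rose and KNG1 fell in both lines.

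The control arrays of both lines show how the lines differ before the siRNA is considered. Huh7 controls held far more of the aldo-keto reductases AKR1C2 (9.23 ± 0.16, adjusted p = 4.13e-11) and AKR1C1 (6.36), the quinone reductase NQO1 (7.99), CTSE (8.12), FGB (7.99), PTGR1 (7.56), HAVCR1 (7.37) and the cytokine receptor OSMR (7.07). RPS6KA3 (6.72) and BRDT (6.53) were higher in Huh7 too. In Hep3B controls AKR1C2, AKR1C1, CTSE, PTGR1, HAVCR1, OSMR and BRDT lay within background and NQO1 at its upper edge, so these differences are lower bounds. Hep3B controls held more of the imprinted SNORD116 small nucleolar RNAs, with SNORD116-17 at -11.14 ± 0.69 (adjusted p = 3.36e-07) and 7 others from -10.58 (SNORD116-15) to -6.49 (SNORD116-8), and of RELN (-7.88) and SLC6A14 (-6.55). Huh7 control means of these RNAs other than SLC6A14 lay within background, so the sizes are bounds, and Huh7 control array 3 read higher than the other 2 for SNORD116-17, SNORD116-15, SNORD116-18 and SNORD116-24. Without that array the values were -12.25 for SNORD116-17, -11.49 for SNORD116-15, -11.41 for SNORD116-18 and -10.53 for SNORD116-24. Without Huh7 control array 1 they were -10.52 for SNORD116-17, -9.93 for SNORD116-15 and -9.64 for SNORD116-18. The liver tumour marker AFP was higher in Huh7 (2.50 ± 0.16, adjusted p = 3.32e-07), and GPC3 lower (-1.57 ± 0.11). ALB was lower in Huh7 (-1.25 ± 0.05), with a Hep3B mean of 19.41 near the ceiling of the deposited values, which compresses the change.

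All 10 metallothionein genes, which bind zinc and copper, were higher in Huh7, also adjusted over the list alone, with a median of 3.10 (adjusted p = 2.76e-14, and adjusted p = 0.0019 with an estimated correlation). It was the 1 list of 18 that held with an estimated correlation. Glycolysis and hypoxia genes were higher in 18 of 28 cases and lower in 2, or 20 and 3 adjusted over the list alone (adjusted p = 6.02e-12, and adjusted p = 0.0536 with an estimated correlation), NRF2 genes in 12 of 20 and lower in 3, or 13 and 3 adjusted over the list alone (adjusted p = 5.73e-09, and adjusted p = 0.116 with an estimated correlation), and histones in 8 of 10, or 9 adjusted over the list alone (adjusted p = 9.34e-06, and adjusted p = 0.116 with an estimated correlation). YAP/TAZ targets, oxidative phosphorylation, MYC targets and the interferon list were higher in Huh7 (adjusted p = 0.000291, 0.00111, 0.00184 and 0.00369), with adjusted p of 0.128, 0.137, 0.136 and 0.197 with an estimated correlation. TGF-beta targets, fatty acid oxidation, epithelial-mesenchymal transition and heat shock genes were higher at adjusted p of 0.0163, 0.019, 0.02 and 0.0275 (adjusted p = 0.136, 0.191, 0.116 and 0.128 with an estimated correlation). Cholesterol genes were higher at 0.0386 and apoptosis regulators at 0.04 (adjusted p = 0.33 and 0.132 with an estimated correlation), and the latter had an adjusted p of 0.0503 without Hep3B siRNA array 1, 0.051 without Hep3B siRNA array 2 and 0.0672 without Huh7 control array 1. Lower in Huh7 were the RNA interference machinery (6 of 9 lower and 1 higher, also adjusted over the list alone), NF-kB genes (10 of 26 lower and 2 higher, 10 and 3 adjusted over the list alone), Wnt targets and ATF4 genes (11 of 29 lower and 2 higher, 12 and 3 adjusted over the list alone), at adjusted p of 0.00186, 0.00728, 0.0163 and 0.02 (adjusted p = 0.116, 0.216, 0.137 and 0.656 with an estimated correlation). Among rows above background 5 lists were called between the lines. In all, 13856 rows differed between the control arrays of the lines, 7303 higher and 6553 lower in Huh7, and 7481 of these were named genes.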

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

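The small RNA tests and the ratio of cell cycle medians were chosen after the results were seen, as were cyclic loess and the test among rows above background.

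Rows of U3, U11 and U12 RNAs rose in both lines, and of 11 U1 rows 11 rose in Hep3B and 9 in Huh7. More short RNA of every kind in the siRNA preparations is argued against by 45 rows of intron-encoded C/D small nucleolar RNAs. A fall of these rows for a reason of their own was not tested, and could hide a general gain. Each had a group mean above the highest background row, but 7 in Hep3B and 3 in Huh7 lay within background in both groups. Over the 45 rows the medians were -0.41 in Hep3B (quartiles -0.64 and -0.09) and -0.40 in Huh7 (lower quartile -0.86). The medians were 0.79 and 0.37 for 55 rows of U3, U13 and small nuclear RNAs other than U6 and 7SK, with their copies. Many of the 55 rows, including all U1, U2 and U7 rows, were named for pseudogenes. Whether probes shared between copies of 1 RNA gave the rises cannot be told from the number of families that rose. Of 10 families 8 had a called rise in Hep3B and 7 in Huh7. The pattern was named for 4 of them after the rises were seen, so a count above 1 was fixed in advance. Outside those 4, U2 rows (medians 2.24 in Hep3B and 1.12 in Huh7) and the U4atac row (3.34 and 2.01) also rose in both lines. U7 and U13 rows had no called rise. Within a family, which copy gave the signal stays open. A change in the cells that follows the siRNA may account for the rise. This stays open as well, since the labels tell apart only 1 siRNA treatment, and loss of the target cannot be told apart from other effects of that siRNA.

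Lists of bright genes (housekeeping, oxidative phosphorylation, ribosomal proteins, glycolysis) were lower in both lines, although with an estimated correlation the Hep3B calls were lost, at adjusted p of 0.0985, 0.0985, 0.0675 and 0.135. A trend of the difference with brightness between arrays is argued against as the whole cause, because 4 of the 4 lists stayed lower in the mean effect after cyclic loess, with adjusted p of 4.33e-08, 6.11e-10, 1.99e-07 and 1.5e-08. A comparison of bright lists with mostly dim rows is argued against likewise, since 4 of the 4 stayed lower among rows above background, with adjusted p of 0.00194, 0.00146, 0.00355 and 0.000421. A lower level of these transcripts per cell in siRNA-treated cells may be a hypothesis, and an unequal total RNA content of the cells was not tested.

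The ATF4 list rose more in Hep3B than in Huh7. A uniformly weaker siRNA effect in Huh7 is argued against by the cell cycle G2/M list, whose median change in Huh7 was 1.18 times that in Hep3B, against 0.467 for the ATF4 list. Members near background in Huh7 are argued against by 17 members above background in the controls of both lines, with a median difference of -0.40. As a set these members were lower by limma camera at the preset correlation (unadjusted p = 9.14e-06). An estimated correlation was not tried for them. The choice of normalization is argued against, since the list stayed called under 3 of 3 other normalizations, though its adjusted p was 0.322 with an estimated correlation. A difference between the lines themselves may underlie it, as a hypothesis from the same data.

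The effect of the siRNA differed between the lines in 1240 rows by the test of the difference, Huh7 minus Hep3B. Named genes with a lower value in Huh7 were RNU1-12P (-2.37), RNU1-13P (-2.37), RNU12 (-2.80), CTSE (-2.07), KIF20A (-0.80), ONECUT1 (-0.91), EREG (-3.11), EGR1 (-2.95), SNORD121B (-2.63), ARRDC3 (-2.44), FGB (-2.33), INSIG1 (-0.71), GDF15 (-1.99), DDIT4 (-1.86), CHAC1 (-1.93), AKR1B10 (-0.82), ODC1 (-0.72), H1-4 (-2.25), H4C3 (-1.37), JUNB (-1.47), SKIL (-0.72), KLF6 (-1.08), HMMR (-0.78), MCM6 (-1.02), CCNE2 (-0.61), FGG (-1.33), FGA (-2.14), ALB (-0.67, with Hep3B levels near the ceiling that compress a change), ACSL4 (-0.74), CPT1A (-0.96), CPS1 (-1.89), GLUL (-0.79) and POLR2A (-1.10). Those with a higher value were ATP10D (2.43), SLC6A14 (1.17), DBR1 (1.24), C5 (0.53), ANKRD1 (0.94), SNORD116-2 (1.81), SNORD116-1 (1.62), PROM1 (1.61), HEG1 (1.56), C3 (0.93), CP (1.06), TTR (1.03), OAS3 (0.62), EIF2AK2 (0.58) and CCN1 (0.90). At least 1 group mean within background limits the differences of RNU12, CTSE, EREG, EGR1, SNORD121B, DDIT4, CHAC1, AKR1B10, JUNB, SLC6A14, ANKRD1, SNORD116-2, SNORD116-1, OAS3 and CCN1. The lists with a lower siRNA effect in Huh7 had median differences of -0.0795 (S phase), -0.0679 (apoptosis regulators), -0.37 (hepatocyte transcription factors), -0.23 (cholesterol biosynthesis), -0.15 (fatty acid oxidation), -0.19 (glycolysis and hypoxia), -0.32 (ATF4), -0.35 (NRF2), -0.30 (MYC targets), -0.17 (oxidative phosphorylation), -0.74 (histones) and -0.0637 (immediate early genes). With an estimated correlation limma camera called 0 of these 12 lists, with 7 lists of all tested at an unadjusted p under 0.05.

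Rows left out of the comparisons also held signal by the same test. Of 1465 exon or junction rows 208 were called in Hep3B and 50 in Huh7, and of 1343 numbered rows 60 and 11. Of 155 spike-in control rows, 1 was called in Hep3B.

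Other splits of the same arrays were counted for each comparison, and in each 1 split, the real one, gave as many called rows. The 10 splits of 6 arrays are too few for a share under 0.05: the real splits called 6810 rows in Hep3B, 5327 in Huh7 and 13856 between the lines, and the highest of the others 0 by limma, with up to 3400, 4299 and 2957 rows at an unadjusted p under 0.05. For the mean effect the real split called 9542 rows, against at most 1240 in 99 others of 100 splits. At an unadjusted p under 0.05 the rows were 16506 against at most 10957. The highest of the other called counts belonged to the split that is the difference between the lines. For the difference 1240 rows were called, against at most 3 in 99 others of 100 assignments of residuals (8298 against at most 6804 at an unadjusted p under 0.05). For both, these counts argue against an arbitrary assignment of the arrays. They cannot exclude chance differences between cultures, which the labels do not tell apart. Mixed splits also hold real effects within their groups, which widens the spread and lowers their counts. The reassigned residuals still hold any difference of effect between the lines, which lowers their counts in the same way.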

How the results depend on the processing

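Camera among rows above background and cyclic loess were chosen after the results were seen. No called list or named gene reversed. Of called rows between lines 52.7% were higher in Huh7, and 47.6% on the deposited values, while in the difference 50.5% were higher, and 42.1% without Hep3B siRNA array 1. Over all alternatives, called lists stayed called in 2013 cases and lost the call in 164, and named genes in 6452 and 100. Requiring 2-fold changes left 1085 rows in Hep3B, 731 in Huh7, 681 in the mean effect, 382 in the difference, 4275 between the lines and 316 shared between lines, since fewer rows can pass. The difference was also 721 after median centring, 1957 with rows below the median left out (fewer rows tested), and 312 with replicate blocks, which cost degrees of freedom. Deviations of same-numbered arrays correlated at 0.117, 0.0599 and 0.0301 in Hep3B and -0.149, -0.124 and 0.105 in Huh7. Those of different-numbered arrays ran from -0.164 to 0.113 in Hep3B and from -0.0702 to 0.203 in Huh7. These values give no clear sign of pairing by number, but cannot rule it out. Huh7 had 2725 rows with its 6 arrays alone. The correlation of effects was 0.592 and 0.620 with rows below the lower quartile or the median left out. Lists called with an estimated correlation were 4 (Hep3B), 12 (Huh7), 0 (difference) and 1 (between lines), and by fry 26 (Hep3B), 28 (mean), 19 (difference) and 29 (between lines). Between lines 11 lists were called with rows below the median left out and 5 among rows above background. Leaving out 1 array gave 616 to 1335 rows in the difference and a correlation of 0.533 to 0.566. Without Huh7 control array 3 SNORD116-17 between lines moved from -11.14 to -12.25, without Huh7 control array 1 to -10.52, and without Hep3B siRNA array 1 SLC7A11 in Hep3B from 2.78 to 3.39. For these values the cause was not tested unless stated. Counts without 1 array were 5072 to 7302 in Hep3B, 3990 to 5249 in Huh7, 8062 to 9314 in the mean effect and 11937 to 14176 between lines. Signal over background limits what can be said of the rows at or under 5.50. The alternatives planned for the target RNA were not run.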

Other observations

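The small RNA groups in this part were chosen after the values were seen, and the counts are of named rows with a group mean above the highest background row.

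U2, U4atac and U6 rows rose with U1, U11 and U12 in both lines. The 3 U2 rows, all named for pseudogenes, rose in both lines, with medians of 2.24 in Hep3B and 1.12 in Huh7. RNU4ATAC, the U4atac RNA of the minor spliceosome, rose by 3.34 ± 0.42 in Hep3B and by 2.01 ± 0.42 in Huh7 (SE, n = 3 arrays per group). U6 RNA is made by RNA polymerase III, and many of its 51 rows are named for pseudogenes. Of the 51 rows, 22 rose in Hep3B and 43 in Huh7, with medians of 0.69 and 0.93, and RNU6-1 rose by 0.86 and 0.93. RNU6-11 and RNU6-37 held the same changes as RNU6-1 in both lines, so the rows are not separate observations. U5 rows rose in 4 of 8 cases in Hep3B and 1 in Huh7, U4 rows in 2 of 4 and, by limma, 0 (also 0 at an unadjusted p under 0.05), and U7 rows in 0 of 19 in both lines (0 and 1 higher at an unadjusted p under 0.05). The U7 rows were all named for pseudogenes, so whether U7 RNA itself changed stays open. Of 88 5S rows 1 rose and 4 fell in Hep3B and 5 fell in Huh7, and of 6 7SK rows 1 fell in Huh7. Of 19 Y RNA rows 2 fell in Hep3B, but by limma 0 after median centring and 1 after cyclic loess. Directions of the called families held on the deposited values, after median centring and after cyclic loess.

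Imprinted clustered C/D small nucleolar RNAs, mainly of the SNORD116 group, fell in 7 of 20 cases and rose in 1 in Hep3B, with a median of -1.11. In Huh7 19 of the 20 lay within background in both groups, so a fall would not have been seen there. MicroRNA rows fell in 20 of 180 cases and rose in 4 in Hep3B, and fell in 4 and rose in 4 in Huh7, with medians of -0.27 and -0.16. H/ACA small nucleolar RNAs, which guide pseudouridylation, fell in 2 of 31 cases in each line. Of 11 Cajal body RNAs 1 fell in Hep3B, and 1 rose and 1 fell in Huh7.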
